A study of Mus musculus with 4 samples.

How the data were processed

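Total RNA of 4 lines of LMTK- cells was measured on the Affymetrix Mouse Genome 430 2.0 Array, with 1 array per line. LMTK- is a mouse fibroblast line of L cell origin that lacks thymidine kinase. Per the labels, 2 lines carried the empty expression vector pCI-neo (vector 1 and vector 2) and 2 were clones that carried the vector with the cDNA of mouse melanotransferrin (MTf 4 and MTf 6). Groups and numbers were taken from the labels. The 2 clones have different numbers, and the labels do not say whether the 2 vector lines were separate clones or cultures. The p-values measure only the spread between these samples, which for the vector lines may be in part technical.

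The deposited values are intensity values on a linear scale, 1 per probe set and array, made with GCOS 1.3 per the submitters' processing notes. The settings of that software are not given in the sources used here, and detection calls were not used. All 4 arrays had the same 2%-trimmed mean signal, 1000.01, so they were used as deposited. Signals reached from 0.1 to 131292, and the share of signals under 32 lay between 15.7% and 17.8% per array. Median signals were 214 in vector 1, 214 in vector 2, 211 in MTf 4 and 209 in MTf 6.

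The table held 45101 probe sets, of which 64 were control probe sets and 45037 were not. The platform annotation paired 34945 of these with 1 gene and 932 with several, and left 9160 unnamed here. Of those with 1 gene, 34741 were found in a gene table of the assembly GRCm38.p6. That table was used to match the genes of the lists and for which genes share a chromosome and neighbour each other. Symbols of named genes came from the platform annotation. Probe sets without a gene, or with several, were given no gene name. Some items are not reported here.

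Signals were converted to log2(signal + 32), so every log2 difference and fold is on that scale, unless stated, and understates changes of dim probe sets. Probe sets with a mean below the median of all non-control probe sets, a signal of about 196, were left out, and 22519 were tested. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), MTf minus vector, with Benjamini-Hochberg adjustment and a threshold of 0.05. Intervals of log2 differences between the groups are 95% intervals of that fit. Other intervals are 95% intervals of a median over genes or probe sets, which share the same arrays and are not replicates. With 2 arrays per group the smallest two-sided exact permutation p is 0.333, so no exact test could reach the threshold, and limma borrows the spread of other probe sets. The number of arrays limits the precision of every value.

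For gene groups, each gene was represented by its probe set with the highest mean, which gave 10682 genes. The 23 gene lists were written before the data were examined. Lists with at least 3 measured genes, 19 in all, were tested with limma's camera, first with a preset correlation between genes of 0.01 and then with an estimated one. The genes of each chromosome were tested the same way. Members of each list were also counted past the threshold over all probe sets tested and adjusted over the list alone. List and chromosome shifts in single arrays are medians of values with no test against replicates, and some were set against random gene lists.

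Named genes followed a rule set before the data were examined. It took Meltf and Tk1, the 15 genes per direction with the largest change past the threshold in both clones against both controls, and, where fewer passed, those with the smallest unadjusted p as values that did not pass. It also took up to 4 members of each list with the smallest p and the follow-up genes recalled from the submitters' related work. Genes named outside the rule are said to be so where they appear.

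The scripts were tested on simulated data for MTf minus vector, with 200 of 22519 probe sets changed in each of 20 simulations. The fit recovered 4.58% of changes of 2-fold, 67.4% of those of 4-fold and 89.1% of those of 8-fold, and 5.00% of its calls were false. Errors were drawn independently for each probe set from the spread that limma had fitted. The real arrays differ in ways that many probe sets share, so these rates need not hold for them. For lists, a shift of 0.5 (log2) in the mitosis list was found in 20 of 20 simulations with the preset correlation and in 0 with the estimated one. An unchanged list whose genes correlated at 0.81 was judged alone, by its p-value without adjustment over the lists. It passed in 60 of 100 simulations with the preset correlation and in 4 with the estimated one. Before adjustment the preset setting thus passed a list of correlated genes too often, and its rate after adjustment was not tested. The estimated setting had little power.

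In all 14 settings were planned before the data were examined, besides 4 that each left out 1 array, and 3 were added after the data were seen. Each result was recomputed under those of them that apply to it. They covered the offset, the filter, normalization, the variance model, the test, the probe set or gene as unit, probe sets with the suffixes x, s or a and the correlation between genes. The test was also run on the 3 splits of the 4 arrays into 2 and 2.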

Results

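The series compared mouse fibroblasts that overexpressed melanotransferrin with fibroblasts that carried the empty vector. Melanotransferrin is an iron-binding protein of the transferrin family that is anchored to the cell membrane. The comparison asks which transcripts differ with its overexpression. There were 2 vector lines and 2 melanotransferrin clones, each on 1 array, and all values are scaled array signals.

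Meltf, the gene of melanotransferrin, was higher in both clones than in both vector lines. Its probe set gave a signal of 1702 ± 259 (SD, n = 2) in the clones and 269 ± 6.08 (SD, n = 2) in the vector lines. Signals were 265 in vector 1, 274 in vector 2, 1519 in MTf 4 and 1885 in MTf 6. The difference was 2.52 on the log2 scale (SE 0.24, 95% interval 1.96 to 3.07), or 5.72-fold. The test of this gene was planned, and taken alone its interval excluded 0. With limma's adjustment over all 22519 probe sets it did not pass the threshold, at an adjusted p = 0.0903. With 1 array left out in turn, its log2 difference lay between 2.36 and 2.67. Whether it passed varied with the array left out, and such fits hold 1 array in a group. The adjustment also depends on other probe sets, so a pass there adds no support for Meltf. Tk1, which encodes thymidine kinase, gave signals of 61.0 in vector 1, 112 in vector 2, 53.2 in MTf 4 and 206 in MTf 6, below the filter.

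Across the array, 1 probe set changed between the clones and the vector lines. This probe set fell from a signal of 2302 ± 308 (SD, n = 2) in the vector lines to 221 ± 0.636 (SD, n = 2) in the clones. Its log2 difference was -3.20 (SE 0.23), with an adjusted p = 0.0304 from limma. It has no gene name here and is given because it was the only call, which was known after its values were seen. A second unnamed probe set, also chosen after its values were seen, was at 1767 in vector 1 and 1921 in vector 2. In the clones it was at 330 in MTf 4 and 225 in MTf 6. The 2 unnamed probe sets have consecutive identifiers on the array, and whether they measure the same transcript was not tested. The second had a log2 difference of -2.62 and an adjusted p = 0.0903 from limma. It passed without MTf 4 (adjusted p = 0.000853) and without MTf 6 (adjusted p = 0.00677), but not without vector 1 or without vector 2. No probe set was called higher by limma. At an unadjusted threshold of 0.05 there were 428 probe sets, 234 higher and 194 lower, where chance alone gives about 1126. The groups did not overlap in 25.8% of the tested probe sets, against 33.3% by chance. The call ended without the filter (adjusted p = 0.173), without the trend (adjusted p = 0.112) and in a per-probe-set test without variance moderation (adjusted p = 1.00).

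**Figure D1:**
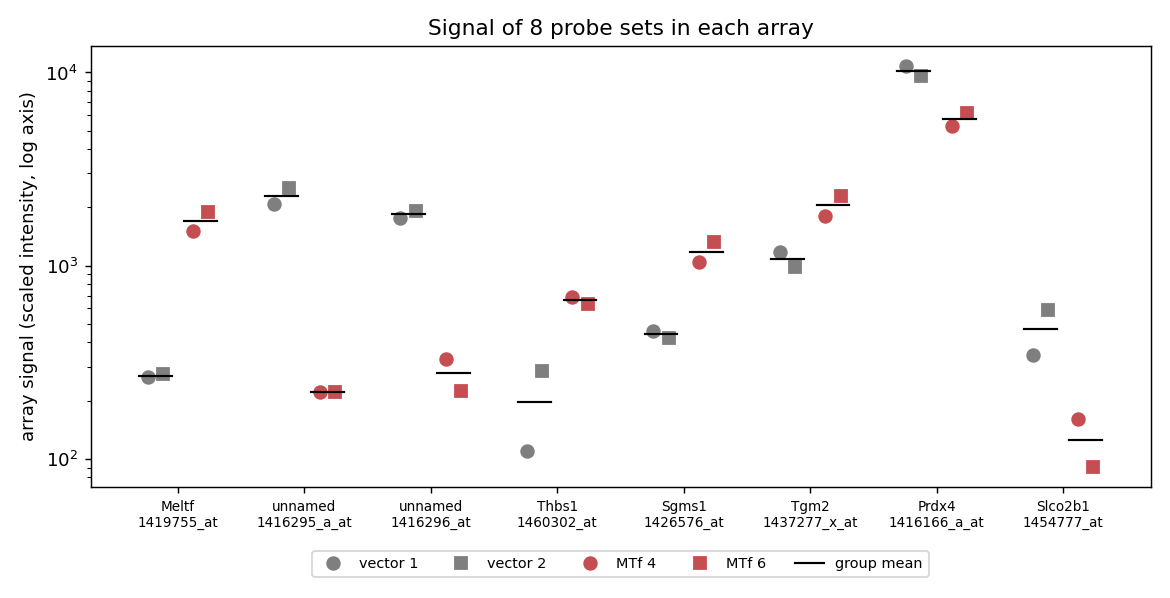
Signal (scaled intensity, log axis) of 8 probe sets in each of the 4 arrays, with vector lines in grey, melanotransferrin clones in red and group means as lines. Meltf sits at 1519 and 1885 in the clones against 265 and 274 in the vector lines, and the called probe set, the first unnamed one, near 221 in both clones.

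None of the other named genes passed the test, so the following are values only, each of 1 probe set. Among genes higher in both clones, Sgms1, which makes sphingomyelin, had a signal of 1181 ± 198 (SD, n = 2) in the clones and 442 ± 26.7 (SD, n = 2) in the vector lines. Thbs1, the matrix protein thrombospondin 1, was at 661 ± 38.5 (SD, n = 2) against 198 ± 125 (SD, n = 2). Tgm2, the crosslinking enzyme transglutaminase 2, was at 2051 in the clones and 1077 in the vector lines. Col27a1, a fibrillar collagen, was at 407 against 107, and Sorbs3, the adhesion protein vinexin, at 905 against 426. The ribosomal protein genes Rpl37a and Rpl39 had log2 differences of 1.45 and 0.92. Creb3l3, a transcription factor of the endoplasmic reticulum, differed by 1.99, Zfp1 by 2.04, Gsap by 1.64 and Gfra1, a receptor for glial cell line-derived neurotrophic factor, by 1.27. Pisd-ps3, a pseudogene, differed by 2.25, Gask1b by 1.32 and 9330102E08Rik by 1.44. Other tested probe sets of the same genes moved little for Sgms1 (log2 differences of 0.11 and 0.07), Rpl37a (0.12 and 0.07) and Gsap (-0.11). Those of Thbs1 (1.06), Tgm2 (0.39 to 0.65) and Pisd-ps3 (0.25 to 0.43) moved the same way as the named ones.

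Among genes lower in both clones, Prdx4, a peroxiredoxin of the endoplasmic reticulum, was at 5724 ± 583 (SD, n = 2) against 10196 ± 863 (SD, n = 2) in the vector lines. Slco2b1, an organic anion transporter, was at 126 against 467, and Hspa4, a chaperone of the Hsp70 family, at 125 ± 126 (SD, n = 2) against 579 ± 13.2 (SD, n = 2). Hspa14, another Hsp70 gene, had a log2 difference of -1.09, Ercc2, a DNA repair helicase, of -1.49 and Mdm4, a regulator of p53, of -1.26. Itsn1, an endocytic scaffold, had a difference of -1.35, Selp, P-selectin, of -1.07 and Fmnl1, a formin, of -1.30. Sae1, of the SUMO activating enzyme, had a difference of -1.11, Ube2w, a ubiquitin conjugating enzyme, of -0.85, Spry4 of -0.75, Srd5a3 of -0.82 and Ankrd9 of -1.28. Afp, alpha-fetoprotein, had a log2 difference of -1.52 by 1 of its probe sets. Within the same genes, other tested probe sets moved little for Prdx4 (-0.08 and 0.05), Hspa14 (-0.14) and Ube2w (-0.12 and 0.03). Those of Hspa4 moved by -0.41 and -0.12, of Mdm4 by 0.26, 0.06 and -0.04 and of Srd5a3 by -0.29, 0.23 and 0.02. Those of Itsn1 reached from -0.58 to 0.07. Other tested probe sets existed for 17 of the 30 named genes, and of these 41 probe sets 31 had the same sign. Only 5 of them, of Pisd-ps3, Thbs1, Tgm2 and Itsn1, were past an unadjusted 0.05 the same way. The median absolute log2 difference of the 41 was 0.12.

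Genes of the interferon response and of antigen presentation were higher as a group in the mean of the clones, through MTf 4, which stood far above the other 3 arrays. Of 26 measured members 21 were higher and 5 lower, with a median log2 difference of 0.24 (camera, adjusted p = 0.00142). With an estimated correlation the list was not called (adjusted p = 0.771). The median deviation from the mean of the 4 arrays was 0.53 in MTf 4, -0.21 in MTf 6, 0.04 in vector 2 and -0.27 in vector 1. MTf 6 thus lay below vector 2, and the list did not part the groups. Igtp, an interferon-induced GTPase, was at 1042 in MTf 4, 450 in MTf 6, 498 in vector 2 and 278 in vector 1. Bst2, an antiviral membrane protein, was at 2763 in MTf 4 and 2213 in MTf 6, against 1628 and 1800 in the vector lines. Rsad2 and Xaf1 had log2 differences of 0.69 and 0.77, and 0 members passed over all probe sets tested or adjusted over the list alone. Without MTf 4 the median was -0.11 (adjusted p = 0.390), and without vector 1 it was 0.06 (adjusted p = 0.371). It was 0.39 without vector 2 and 0.66 without MTf 6.

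Genes of cholesterol synthesis were lower as a group in the clones, with MTf 4 below the other 3 arrays. Of 19 measured members 17 were lower, with a median of -0.20 (camera, adjusted p = 0.00191). This call too ended with an estimated correlation (adjusted p = 0.771). The median deviation was -0.19 in MTf 4, 0.025 in MTf 6, 0.058 in vector 1 and 0.097 in vector 2. MTf 6 thus lay below both vector lines, but by far less than MTf 4. Sc5d was at 2961 in MTf 4 and 3815 in MTf 6, against 4364 and 4655 in the vector lines, and Hmgcs1, the cytosolic HMG-CoA synthase, had a log2 difference of -0.30. Idi1 and Msmo1 had differences of -0.35 and -0.28, and 0 members passed over all probe sets tested or adjusted over the list alone. Without MTf 4 the median was -0.05 (adjusted p = 0.676), without vector 2 it was -0.14 (adjusted p = 0.0618) and without MTf 6 it was -0.31.

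Genes of mitosis were also lower as a group, by a smaller amount. Of 29 measured members 24 were lower, with a median of -0.14 (camera, adjusted p = 0.00310), and with an estimated correlation the call ended (adjusted p = 0.771). The list stood at 0.30 in vector 1 and 0.11 in MTf 6, and at -0.12 in vector 2 and -0.28 in MTf 4, so it did not part the groups. Tpx2, a spindle assembly factor, was at 7237 in vector 1, 3969 in vector 2, 2542 in MTf 4 and 4336 in MTf 6. Bub1b, of the spindle checkpoint, had a log2 difference of -0.44, Cenpf, a kinetochore protein, of -0.40 and Kif23, a kinesin of cytokinesis, of -0.31. Again 0 members passed over all probe sets tested or adjusted over the list alone. The median was 0.05 without vector 1 and 0.04 without MTf 4, but -0.36 without vector 2 and -0.30 without MTf 6.

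Genes of DNA replication differed within the groups more than between them. Of 28 measured members 25 were lower in the clones, with a median of -0.13 that did not pass (camera, adjusted p = 0.0932; adjusted p = 0.831 with an estimated correlation). The list stood at 0.45 in vector 1 and 0.30 in MTf 6, and at -0.32 in vector 2 and -0.42 in MTf 4. Uhrf1, which maintains DNA methylation, was at 7942 in vector 1, 4048 in vector 2, 3162 in MTf 4 and 6231 in MTf 6. Ccne2, cyclin E2, was at 1548, 1156, 564 and 1597 in the same order, and Rrm2 and Pold1 had log2 differences of -0.30 and -0.34. The group difference took either sign with 1 array left out. Its median was 0.24 without vector 1 and 0.22 without MTf 4, but -0.51 without vector 2 and -0.52 without MTf 6.

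Genes of iron handling, the field of melanotransferrin itself, showed no call. Of 25 measured members 7 were higher and 18 lower, with a median of -0.12 (camera, adjusted p = 0.296). Flvcr1, a heme exporter, was at 2368 in MTf 4 and 2533 in MTf 6, against 4214 and 2965 in the vector lines. Pcbp2, an iron chaperone, had a log2 difference of 0.25, Ncoa4, a receptor for the autophagy of ferritin, of -0.25 and Nfs1, of iron-sulfur cluster assembly, of 0.24. Tfrc, the transferrin receptor, chosen after its values were seen, had a difference of -0.01 (95% interval -0.72 to 0.70). Genes of hypoxia and iron depletion had a median of -0.06 over 26 members, 18 of them lower (adjusted p = 0.0966). In each of these lists 0 members passed over all probe sets tested or adjusted over the list alone.

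None of the other lists was called, and 0 of their members passed over all probe sets tested or adjusted over the list alone. Median log2 differences were 0.05 for p53 targets and CDK inhibitors (18 genes), 0.01 for extracellular matrix (22 genes) and 0.01 for plasminogen, proteases and their inhibitors (20 genes). They were 0.08 for adhesion and migration (23 genes), -0.09 for chemokines and inflammatory signals (14 genes) and 0.08 for the unfolded protein and integrated stress response (28 genes). They were 0.03 for antioxidant and metal-binding genes (27 genes), -0.04 for targets of TGF-beta, BMP and Wnt (13 genes), 0.07 for immediate-early genes (20 genes) and -0.04 for fibroblast and mesenchymal genes (17 genes). For the targets of TGF-beta, BMP and Wnt the mean was 0.14, opposite in sign to the median. Markers of other cell types had medians of -0.19 for macrophage, 0.04 for muscle and 0.01 for adipocyte genes, with 4 genes each. Melanocyte, epithelial and endothelial markers had 2 measured genes each, too few for the test, with medians of 0.45, -0.15 and -0.06.

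**Figure D2:**
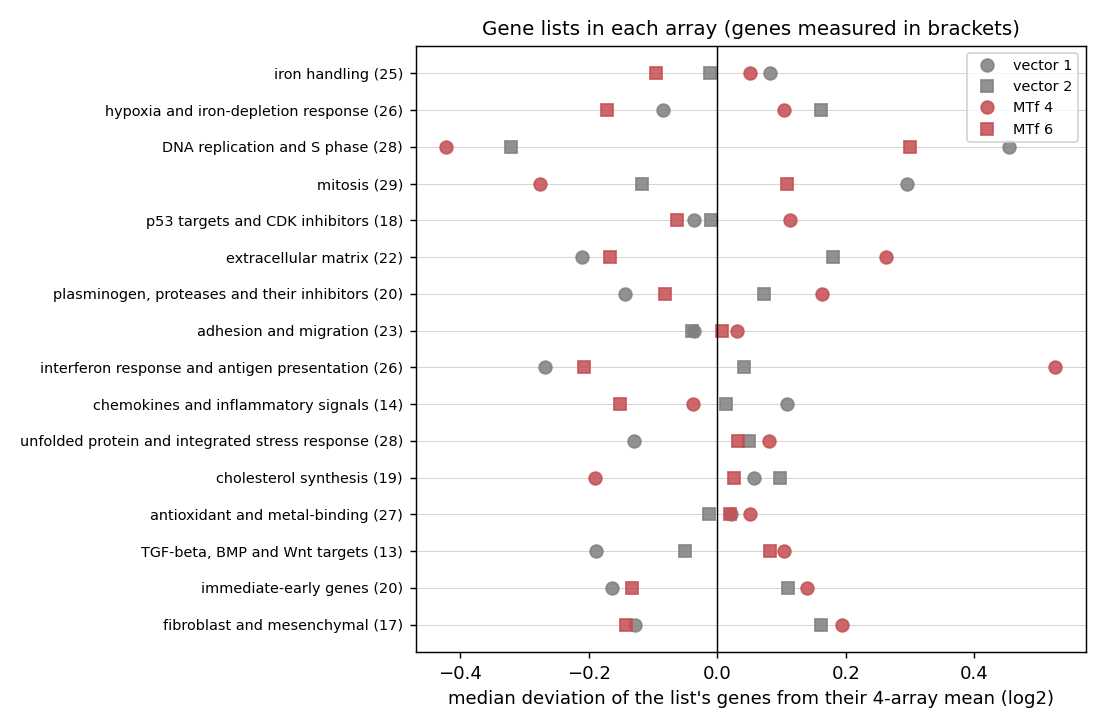
Median deviation (log2) of the genes of 16 lists from their mean over the 4 arrays, 1 point per array, with the number of measured genes in brackets. For DNA replication, vector 1 and MTf 6 lie at 0.45 and 0.30 and the other arrays at -0.32 and -0.42. For the interferon list MTf 4 alone lies far to the right, at 0.53.

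Mef2a and Tcf4, transcription factors among the follow-up genes, did not differ past the threshold. By its probe set with the highest mean, Mef2a was at 5422 in vector 1, 10575 in vector 2, 10263 in MTf 4 and 5933 in MTf 6, a log2 difference of 0.04 (95% interval -0.80 to 0.89). Tcf4, also by its probe set with the highest mean, differed by 0.10 (95% interval -0.55 to 0.75). Apod, apolipoprotein D, was below the filter by both probe sets. It was at 68.2 in vector 1, 35.0 in vector 2, 108 in MTf 4 and 31.9 in MTf 6 by 1 of them, and the log2 difference was 0.21 by this and -0.23 by the other. This list may have been chosen on these arrays, so it is not independent evidence, and 0 of its members passed over all probe sets tested or adjusted over the list alone.

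Differences between lines of the same group were as common as differences between the groups. Signals differed at least 2-fold for 1074 probe sets between the 2 clones and for 751 between the 2 vector lines, and for 549 to 930 between a clone and a vector line. Each line was hybridised once, so these differences have no replicate check. Aldh1a7, an aldehyde dehydrogenase, was at 5530 in MTf 6 and 138 in MTf 4, a 32.8-fold difference. Cp, the ferroxidase ceruloplasmin, was at 65.3 in MTf 6, 2789 in MTf 4, 749 in vector 1 and 2038 in vector 2, and all 5 of its tested probe sets were lower in MTf 6 than in MTf 4. Bche, butyrylcholinesterase, was at 193 in MTf 6 and 2040 in MTf 4, and Dpt, the matrix protein dermatopontin, at 196 and 1903. Gbp6, an interferon-induced GTPase, was at 2168 in MTf 4 and 83.0 in MTf 6. Between the vector lines, Diaph2, a formin, was at 14966 in vector 1 and 324 in vector 2, a 42.2-fold difference, and Tead4, a transcription factor of the Hippo pathway, at 2455 and 105. Col8a1 was at 10147 in vector 2 and 1919 in vector 1. These 8 genes were among those with the largest differences and were named after their values were seen.

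Genes of chromosomes 4 and 10 were higher as groups in the clones, and each shift came from 1 array. On chromosome 4, 493 of 641 genes were higher, with a median log2 difference of 0.14, and on chromosome 10, 381 of 512, with a median of 0.16 (camera, adjusted p = 5.39e-10 for both). With an estimated correlation neither was called (adjusted p = 0.838 for both). Against the other 3 arrays, chromosome 4 genes stood at 0.32 in MTf 6 (95% interval over the genes of this array 0.29 to 0.35), and chromosome 10 genes at -0.36 in vector 2 (95% interval, likewise over genes, -0.38 to -0.31). Cdk4, the cell cycle kinase, which lies on chromosome 10 and was named after its values were seen, was at 7306 in vector 2 and at 18253, 16338 and 17300 in vector 1, MTf 4 and MTf 6. Its own shift in vector 2 was -1.26, far beyond the chromosome's median of -0.36, so it is not typical of the chromosome. Without MTf 6 the median of chromosome 4 was 0.02, and without MTf 4 it was 0.31. For chromosome 10 it was 0.0044 without vector 2 and 0.33 without vector 1.

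**Figure D3:**
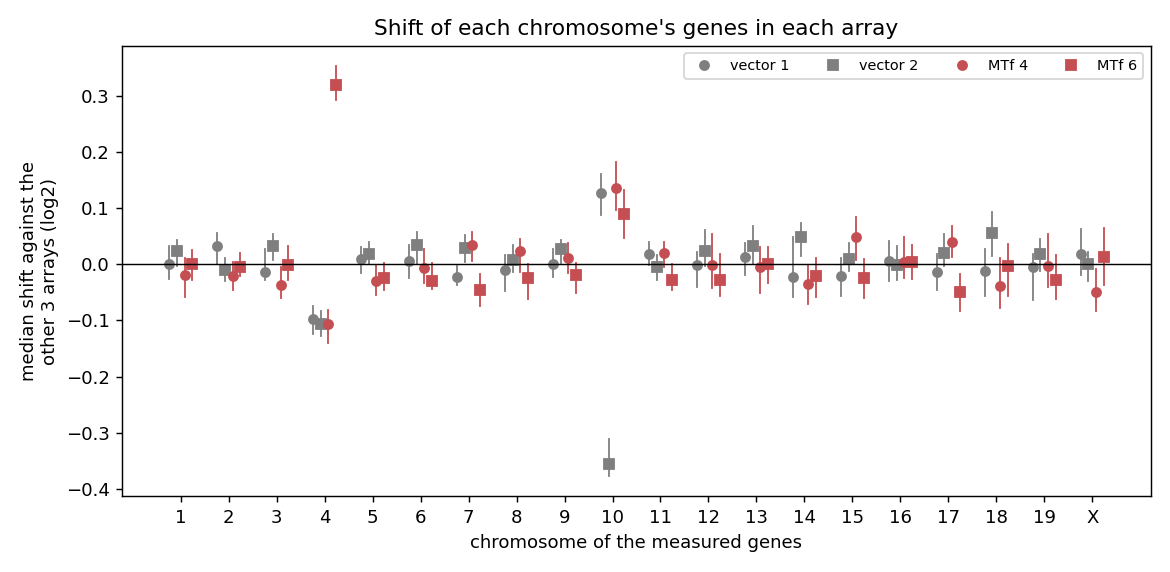
Median log2 shift of the measured genes of each chromosome in each array against the other 3 arrays, with 95% intervals of the median over genes. Chromosome 4 stands at 0.32 in MTf 6 and chromosome 10 at -0.36 in vector 2.

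The 3' over 5' signal ratio of the Actb control probe sets was 1.23 in vector 1, 1.22 in vector 2, 1.21 in MTf 4 and 1.31 in MTf 6. For Gapdh it was 0.683, 0.691, 0.681 and 0.669 in the same order. The spiked-in bioB control was at 1307, 1545, 1655 and 1428, and the dap control at 2157, 3133, 1451 and 2820. The Gapdh ratio was lower in both clones than in both vector lines, by a margin of the third decimal in MTf 4, and the other 3 measures did not part the groups.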

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

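A middle probe set (MB) of the pyruvate carboxylase control group, which no comparison of the report uses, was higher in both clones than in both vector lines. Its signals were 171 in vector 1, 146 in vector 2, 270 in MTf 4 and 265 in MTf 6, so the lower clone was 1.55-fold above the higher vector line. The other middle probe set (MA) was at 232, 370, 298 and 301 in the same order and did not part the groups. Some other control probe sets were also higher in both clones, and many did not part the groups. Among the former, the 3' probe set of 18S rRNA was at 778 and 828 in the vector lines and 845 and 1405 in the clones. By chance the groups part, in either direction, in 33.3% of probe sets. No biological explanation was tested.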

How the results depend on the processing

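The labels pair no arrays of the 2 groups, so no pairing was planned. Where 1 array was left out, the lone array of its group was assumed to vary like the other group. The number of calls depended on the settings. The 1 lower probe set became 0 without the filter, with only probe sets above the 75th percentile, without the trend, in a per-probe-set test without variance moderation, with gene means and without probe sets with the suffixes x, s or a. The filter at the 75th percentile removed the called probe set, gene means left it out because it has no gene name, and the last of these removed it by its suffix a, which does not mark cross-hybridisation with other genes. Without the filter the adjustment ran over 45037 probe sets instead of 22519. Without variance moderation, 2 residual degrees of freedom leave little chance to pass over 22519 probe sets. Beyond this the cause was not tested, nor was it for the setting without the trend. A fold rule called 11 higher and 7 lower, but 60 and 11 when vector 2 and MTf 4 were set against vector 1 and MTf 6, and 4 and 7 in the third split. Leaving out 1 array gave 1 to 7 higher and 1 to 18 lower, most without MTf 4. Array pairs as blocks, chosen after seeing the data, gave 2 higher and 2 lower (vector 1 with MTf 6) and 1 higher and 2 lower (vector 1 with MTf 4). In both, the second unnamed probe set passed (adjusted p = 0.00266 and 0.0420). In both, Meltf kept its log2 difference of 2.52 and passed, with adjusted p = 0.00280 and 0.0420, within a range of 0.00280 to 1.00 over its 13 alternatives. With 1 array left out Meltf lay between 2.36 and 2.67, and over the 13 alternatives between 2.40 and 2.65. Meltf had no value above the 75th percentile.

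With an estimated correlation 0 lists were higher, 0 lower and 0 chromosomes higher. Leaving out 1 array gave 1 to 2 lists higher, 1 to 3 lower and 1 to 2 chromosomes higher. Without the filter 6277 probe sets differed 2-fold between the vector lines and 6829 between the clones, since dim probe sets then count.

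Many list medians near 0 changed sign, and for these the cause was not tested. The plasminogen and protease list was -0.079 without the filter, -0.038 above the 75th percentile, -0.025 with quantile normalization, -0.0084 with cyclic loess, -0.012 with gene means and -0.066 without chromosomes 4 and 10. The antioxidant list was -0.012 with quantile normalization, -0.0034 with gene means and -0.012 without those chromosomes. Muscle genes were at -0.14 without the filter and -0.024 without those chromosomes. The p53 list was -0.0042 without the filter, adipocyte genes -0.035 above that percentile, TGF-beta targets 0.0063 with quantile normalization and extracellular matrix -0.00066 with cyclic loess. Leaving out chromosomes 4 and 10 was chosen after seeing the data.

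With 1 array left out, medians reached from -0.20 to 0.087 for hypoxia, -0.52 to 0.24 for DNA replication, -0.36 to 0.049 for mitosis, -0.031 to 0.16 for p53 targets and -0.21 to 0.27 for extracellular matrix. They reached from -0.038 to 0.18 for proteases, -0.11 to 0.66 for interferon, -0.045 to 0.15 for unfolded protein, -0.027 to 0.078 for antioxidant, 0.055 to 0.18 for TGF-beta targets and -0.11 to 0.23 for immediate-early genes. They reached from -0.19 to 0.19 for fibroblast, -0.35 to 0.34 for macrophage, -0.25 to 0.36 for muscle and -0.13 to 0.27 for adipocyte genes. DNA replication, not called with all arrays, passed in all 4 settings that left out 1 array, with either sign. Other lists not called with all arrays passed with 1 left out for hypoxia (-0.17 without vector 1, -0.20 without MTf 4), extracellular matrix (0.22 without vector 2, 0.27 without MTf 6) and chemokines (-0.13 without vector 2). Chemokines also passed with gene means, at -0.19. All these passes rest on the preset correlation, and with all arrays and an estimated one the adjusted p was 0.901 for extracellular matrix, 0.831 for DNA replication and 0.771 for hypoxia and for chemokines.

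Of 61 probe sets named by the rule or as follow-up genes, 11 changed sign, and of 62 further list members 18 did. With 1 array left out, Uhrf1 reached from -0.84 to 0.14 and Ccne2 from -1.20 to 0.25. By the 4 of its probe sets that changed sign, Mef2a reached from -0.44 to 0.52, -0.71 to 0.25, -0.25 to 0.21 and -0.45 to 0.46. By its 5 tested probe sets, Tcf4 reached from -0.18 to 0.38, -0.38 to 0.46, -0.40 to 0.29, -0.57 to 0.55 and -0.38 to 0.25, and the fourth of these probe sets was at 0.0039 with quantile normalization. Without MTf 4, Hspa4 (-3.17) and Gask1b (1.63) passed, in a fit that holds 1 clone.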

Other observations

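Several genes with values of interest fell outside the rule for named genes, and all were chosen after their values were seen. Sdc2, the heparan sulfate proteoglycan syndecan 2, was higher in both clones by 3 tested probe sets, with log2 differences of 0.87 to 1.11 and no adjusted p under 0.05. By 1 of these its signals were 2998 in vector 1, 4518 in vector 2, 5911 in MTf 4 and 7769 in MTf 6. Ccn1, a matricellular protein also known as Cyr61, was higher by 4 probe sets, with differences of 0.91 to 1.14 and no adjusted p under 0.05. Without MTf 6, 2 of them stood at 1.67 and 1.44, so MTf 4 carried much of the difference. By the brightest it was at 23817 in MTf 4, 11445 in MTf 6 and 6981 and 8004 in the vector lines. Afp, a protein of fetal liver and yolk sac, was abundant in all 4 arrays by its brightest probe set, with signals of 15810 to 24501. That probe set had a log2 difference of -0.12, where the Afp probe set named in the report had -1.52.

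Of the tests below, those of the splits, the growth state, RNA degradation, signal level and the share of each difference kept after cyclic loess were chosen only after the result was seen. The tests by window and by the other values after cyclic loess were set before their own values were seen, but after the patterns themselves had been noticed.

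Of the 3 splits of the 4 arrays into 2 and 2, 2 called at least as many probe sets as the split by group. The split by group called 1, and the highest of the others called 102. With 3 splits no share under 0.05 can be had. The split that set vector 2 and MTf 4 against vector 1 and MTf 6 had 3735 probe sets at an unadjusted threshold of 0.05, against 428 for the groups, which points to a structure of the samples. The remaining split called 0, with 388 at that threshold.

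That structure was also the first principal component, with 48.7% of the variance, against 26.6% for the component that parted the groups. After cyclic loess that split called 53 probe sets, all among the 102, against a bound of 51 set beforehand. Over the 102, a median of 99.5% of each log2 difference was kept (95% interval 99.0% to 100.3%), while the differences of all tested probe sets moved by a median of 0.03. These values argue against a level-dependent curve between the arrays as the cause. Over the 102 the median adjusted p was 0.0387 before and 0.0495 after, with a highest of 0.0619, and the median SE was 0.158 before and 0.159 after. Why the other calls ended was not tested further. RNA degradation stays open, since 1 of the 2 control genes, Actb, put vector 1 and MTf 6 above the others and Gapdh gave no such order. The Actb order rests on a small margin for vector 1, at 1.229 against 1.221 in vector 2, with 1.307 in MTf 6. A difference in the growth state of the cultures stays open too. The DNA replication list lay outside the middle 95% of random lists in 4 of 4 arrays, on opposite sides in the 2 pairs, but its genes correlate at 0.92, so random lists are no fair reference, and its values had been seen before. The lists of mitosis, extracellular matrix and fibroblast genes did the same, 4 of the 19 lists in all, and no label gives density or day of harvest.

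Chromosome 4 genes stood high in MTf 6. Random lists matched on signal level reached the shift in 0% of 10000 draws, and their most extreme median was 0.05. After cyclic loess the shift was 0.33, so neither signal level nor a level-dependent curve accounts for it. All 25 windows of 25 or more neighbouring genes, 100% of them, were shifted up, with medians of 0.11 to 0.48. A gain of the chromosome in that clone may explain this, as a hypothesis, and DNA copy number was not analysed here.

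Chromosome 10 genes stood low in vector 2. Matched random lists reached that shift in 0% of draws, with a most extreme median of -0.05, and after cyclic loess it was -0.36. Of 20 windows 19, or 95%, were shifted down, and the exception, from H60c to Shprh, stood at 0.38. The lowest window, from Ppm1h to Shmt2, stood at -0.96 and holds Cdk4 and Ddit3. A loss of part of the chromosome in that vector line may explain this, as a hypothesis, and it would make a control line, not the clones, the source of the group difference.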
